A study of Mus musculus with 2 samples.

How the data were processed

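SVZ tissue of wild-type and CNP-hEGFR mice at postnatal day 8 was microdissected, and its RNA was copied into biotin-labelled cRNA and hybridised to a neurogenesis and neural stem cell oligonucleotide array, per the labels' protocols. The series holds 2 samples, 1 per group. The series' design text speaks of 3 RNA preparations with repeat assays, while the deposited report names 2 arrays in all, 1 per group. Repeat assays were not analysed here.

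The deposited intensity of each spot is the average over its area, with a local background intensity beside it, and no background was subtracted from either, per the file headers. The deposited normalized values are a ratio, the spot intensity minus the array minimum over that of the mean of 9 normalization spots (3 of Ppia, 3 of B2m, Rps27a, Hsp90ab1 and the 12S rRNA), per the file headers, and a further column gives the authors' ratio of CNP-hEGFR over wild-type. The design text names Gapdh, Ppia and β-actin for normalization instead, and GEArray Expression Analysis Suite 2.0 as the software. The series' value table equals the deposited normalized values at 2 decimals for all 288 spots. The deposited present and absent calls used a threshold of 1.5, per the file headers. No rule that turns intensities into these calls was found: 20 combinations of a factor and a background reference were tried per array, and the closest differed from the deposited calls at 13 of 274 spots in wild-type and 12 in CNP-hEGFR. Other references tried earlier did not give them either. Spots with a bleeding warning are marked in a further deposited table.

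Intensities were read from the deposited raw table, with 263 gene spots, 11 spots of 5 housekeeping genes, 1 rRNA spot and 13 control spots. Each intensity was divided by the mean of the 3 Gapdh and 3 Ppia spots on the same array, as the design text states, except that β-actin was not analysed here. The log2 ratio is CNP-hEGFR over wild-type. Genes called present on at least 1 array were used. A gene present on 1 array only has a bound, written as at least N-fold: the brighter value over the higher of the dim spot's own value and a floor (5090 in wild-type, 10178 in CNP-hEGFR). The floor is the lowest intensity on that array among genes called present in both the call sheet and the layout sheet, without the 9 genes whose deposited values do not follow from the array, 5 of whose present values lie below it. No bound was given where it fell under 1-fold. A gene at 99% or more of the ceiling of 65535 on both arrays got no ratio, and one at it on 1 array a bound. The 3 genes with an intensity above the ceiling, which are among the 9, were not treated as saturated and kept a ratio of the values as deposited. These steps left 101 genes, 84 with a ratio and 17 with a bound. No test was possible with 1 array per group.

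For the fixed gene lists with at least 3 measured members, the median log2 ratio was given with its percentile among 10000 random lists of the same size drawn to match on 3 bins of mean log2 intensity, as a description of these 2 arrays. Of 17 lists fixed before the data were examined, 3 had no gene among those analysed and 2 had enough measured members, the Notch ligands and the growth factors. The genes named are, by a rule fixed before the data were examined, the 10 largest and 10 smallest ratios among genes present on both arrays, the 10 brightest genes present on 1 array with a bound of at least 2-fold, the core Notch and EGF receptor genes, the 2 members of each list farthest from 0, and the housekeeping genes. Ascl2, Nkx2-2, Fezf2, Spock2, Fgf2, Hes6, Cspg4, Erbb3, Erbb4, Nrg1, Sox3 and the genes named only in the added lists fall outside this rule and were chosen after their values were seen. Some genes that the rule takes are not reported here, and counts include them.

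Chosen after the data were seen were the 99% and 95% marks for spots at or near the ceiling, the lowest present intensity as the floor of a bound, the 3 bins of intensity, the set of 9 genes, the block at the left edge of the layout, 5 further gene lists and 6 further alternatives. Symbols were taken from the deposited tables. Accessions of 253 of the 263 genes matched the RefSeq table of mouse assembly GRCm38.p6 without version numbers, and 14 of these genes have a newer symbol there.

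The ratio, count and list steps were tested on simulated arrays of 260 genes for the CNP-hEGFR over wild-type comparison, with 1 array made 2 times as bright, the ceiling imposed, and 20 genes raised 4-fold. All 20 passed 2-fold under Gapdh and Ppia scaling and under array-median scaling, and 0 unchanged genes did. The simulated noise was smaller than the spread on the real arrays, where unscaled log2 ratios had an interquartile range of 0.55 to 1.31. Every simulated spot was called present, so bounds from the floor were not exercised, and only genes dim in wild-type were raised. The 0 therefore does not carry over to the counts on the real arrays. The unchanged genes had a median log2 ratio of 0.62 under Gapdh and Ppia scaling and -0.19 under array-median scaling.

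The alternatives were array-median scaling, Gapdh or Ppia alone, the value table, the report's normalized values, other filters on calls and bleeding, subtraction of the blank spots, and thresholds of 1.5-fold and 3-fold. The further alternatives were leaving out the 9 genes (also with array-median scaling), the Gapdh and Ppia spots below 95% of the ceiling, scaling by local background, and the layout sheet's calls. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures were drawn with Matplotlib 3.10.9.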

Results

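Gene expression was profiled in the subventricular zone (SVZ), the germinal layer lining the lateral ventricles of the mouse brain, at postnatal day 8. Wild-type tissue was compared with tissue of CNP-hEGFR mice, a transgenic line in which a human EGF receptor is expressed from the promoter of the oligodendrocyte gene Cnp. Each group is represented by 1 array of 288 spots, 263 of them for genes of neurogenesis and neural stem cell biology. The median gene spot had an intensity of 3908 in wild-type and 8528 in CNP-hEGFR. Because there was 1 array per group, no value below has a replicate check, no test was made, and the number of arrays limits the precision. A 2-fold difference is used as a size only.

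Of the 263 genes, 91 were called present in wild-type SVZ and 103 in CNP-hEGFR SVZ by the deposited calls, against 11 and 12 with an intensity above the mean plus 2 SD of the 2 blank spots. Both arrays called 88 genes present, 15 were present only in CNP-hEGFR, 3 only in wild-type, and 157 on neither array. Among the genes without a present call on either array were the Notch receptor Notch2 and all 4 members of the EGF receptor list, Erbb2, Erbb3, Erbb4 and the ligand Nrg1. Egfr itself, Notch1, Notch3, Notch4, Jag2, Hes1, Hey1, Hey2 and Rbpj were not analysed here.

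The comparison asked how the SVZ of mice with the EGF receptor transgene differs in expression from wild-type SVZ. Most genes had higher values in CNP-hEGFR. After division by Gapdh and Ppia, 50 of the 101 genes with a ratio or a bound were at least 2-fold higher in CNP-hEGFR, and 2, the Notch ligands Dll1 and Jag1, were at least 2-fold lower. Without 9 genes whose deposited values do not follow from the array, described further on, 48 were higher and 0 lower. The whole set of 263 genes had a median log2 ratio of 0.83, a 1.78-fold difference, and relative to that median 8 genes were at least 2-fold higher and 6 lower (7 and 2 without the 9 genes). Scaling each array to its median gene spot in place of Gapdh and Ppia gave 8 genes higher and 8 lower, so the share of higher genes among those past 2-fold went from 96.2% to 50.0%. Among the 85 genes with a value that were present on both arrays, 39 were higher and 2 lower, and division of each spot by its own local background left 2 genes at least 2-fold higher, Numb among them and both among the 9, and 6 lower, 4 of them among the 9 and the others Spock2 and Sema6c.

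Outside the 9 genes, the highest ratios among genes present on both arrays belonged to Sepp1 (log2 ratio 2.11), which encodes the selenium carrier selenoprotein P, Dlg4 (2.10), the postsynaptic scaffold PSD-95, and Gpr98 (2.09), the adhesion receptor now named Adgrv1. Relative to the median of all genes the ratios were 2.42-fold, 2.40-fold and 2.40-fold. These genes are present by the deposited calls, but their wild-type intensities of 8799, 5444 and 5187 lay below the mean of the blank spots (17762). In CNP-hEGFR Dlg4 (25954) and Gpr98 (24669) lay below that array's mean as well (31233). These folds therefore do not rest on signal above the mean of the blanks on both arrays. The 2 blank spots differed, at 27046 and 8478 in wild-type and 39739 and 22727 in CNP-hEGFR. In the layout they lie directly below Trappc4 and Twist1, bordering the left-edge block described below, where local background was raised. Their level in CNP-hEGFR may therefore not hold for the rest of the array. Sepp1 passed the dimmer blank on both arrays, Dlg4 and Gpr98 in CNP-hEGFR only. The galanin receptor gene Galr2 (1.75), the polarity gene Pard3 (1.60), the homeobox gene Pitx3 (1.55), the laforin gene Epm2a (1.53) and Lst1 (1.51) followed, each under 2-fold once set against the median of all genes. All of them lay below the mean of the blanks in wild-type, and Galr2 (20633), Pitx3 (24003) and Lst1 (16974) in CNP-hEGFR as well. Under division of each spot by its own local background, Sepp1 had a log2 ratio of -0.26, Dlg4 0.62 and Gpr98 0.47.

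Among the genes called present only in CNP-hEGFR, 11 were at least 2-fold higher. The brightest were Twist1, a mesodermal transcription factor gene, at least 6.07-fold higher, Trappc4, a vesicle-transport gene, at least 5.12-fold, Mtss1, at least 4.80-fold, and Twsg1, a BMP-binding protein gene, at least 3.92-fold. Relative to the median of all genes these bounds were 3.41-fold, 2.87-fold, 2.69-fold and 2.20-fold. The morphogen gene Shh was at least 2.70-fold higher, Cables1 2.61-fold, Gdf7 2.36-fold, Ppp1r9b 2.25-fold, the plexin gene Plxna4 2.25-fold and the neurotrophic receptor gene Gfra3 2.16-fold. Relative to the median of all genes, these bounds were 1.52-fold or less. Of these 10 genes, only Twist1 (34429) was brighter in CNP-hEGFR than the mean of the blank spots (31233). The other bounds rest on spots not above the mean of the blanks on either array. Trappc4 (29044) and Mtss1 (27219) were brighter than the dimmer blank in CNP-hEGFR (22727). The spots of Twist1, Trappc4, Twsg1 and Sepp1 lie in a block at the left edge of the array layout, where the local background was raised as well, by 8.39-fold around Twist1, 8.76-fold around Trappc4, 4.13-fold around Twsg1 and 5.78-fold around Sepp1. Mtss1 lies outside this block, and its local background was 4.78-fold higher. These background folds are unscaled and have no floor, unlike the bounds above. Without scaling or floor, the spots rose 9.93-fold (Twist1), 7.12-fold (Trappc4), 5.20-fold (Twsg1), 4.81-fold (Sepp1) and 7.29-fold (Mtss1). Twist1, Twsg1 and Mtss1 thus rose more than their local background, Trappc4 and Sepp1 less.

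Among genes present on both arrays, the lowest ratios outside the 9 genes were close to 0. Stmn1, which encodes the microtubule-destabilising protein stathmin, had a log2 ratio of -0.21, 4732435N03Rik (now Csgalnact1) -0.10, the semaphorin gene Sema6c -0.07, the drebrin gene Dbn1 -0.01, Runx3 0.04 and Cdk5rap3 0.14. Relative to the median of all genes, Stmn1 was 2.06-fold lower in CNP-hEGFR and Sema6c 1.87-fold lower. Fezf2, a forebrain transcription factor gene called present only in wild-type, had a lower value than these, a bound of -0.40, or -1.23 relative to the median of all genes. Several of these genes were bright on both arrays: Stmn1, Dbn1 and Runx3 had wild-type intensities of 56052, 56730 and 56487 against a ceiling of 65535, which leaves Stmn1 no more than a 1.17-fold rise. The 11 genes outside the 9 that were present on both arrays, had a ratio or bound and were brighter than 32768 in wild-type had a median log2 ratio of 0.17, and the 65 dimmer ones 1.06.

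Spots that carry no mouse gene were also brighter in CNP-hEGFR. All 10 control and blank spots below the ceiling were brighter, by 1.42-fold to 3.13-fold with a median of 1.94-fold, and the local background around the gene spots was 1.87-fold higher at the median. Gene spots themselves were 1.99-fold brighter before scaling. Across the 254 genes outside the 9, which are not independent replicates, the log2 ratio of the spot and that of its local background had a Pearson correlation of 0.82 and a Spearman correlation of 0.78. Local background is not independent of spot signal. In wild-type it was 61755 beside a Gapdh spot of 65465, against an array median of 3742. The mean of the 6 Gapdh and Ppia spots rose by a factor of 1.11 only. Of these spots 3 stood near the ceiling on both arrays, with ratios from 1.00 to 1.02, while the other Ppia spots had ratios of 1.38 and 1.39 and the other Gapdh spot 1.15. That Gapdh spot was not called present on either array. It was dimmer than its local background, at 23793 against 25097 in wild-type and 27388 against 27822 in CNP-hEGFR. Among the housekeeping genes not used for scaling, the dimmest B2m spot was 1.61-fold and Rps27a 4.85-fold brighter in CNP-hEGFR, and Hsp90ab1, at the ceiling, had a ratio of 1.00.

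**Figure D1:**
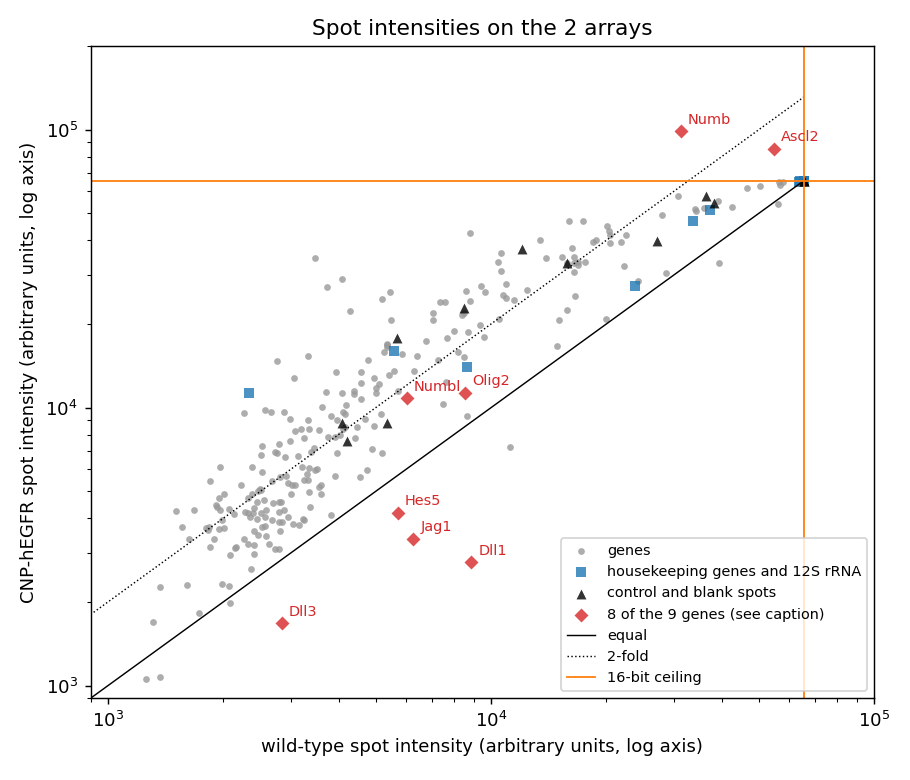
Intensity of the spots on the wild-type array (x axis, arbitrary units, log scale) and on the CNP-hEGFR array (y axis, same units, log scale), with genes in grey, housekeeping spots in blue, control and blank spots in black, 8 of the 9 genes whose deposited normalized values do not follow from their intensities in red, and the 16-bit ceiling of 65535 in orange. Most genes and control spots lie between the equal line and somewhat above the 2-fold line, and Ascl2 and Numb lie above the ceiling in CNP-hEGFR.

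**Figure D2:**
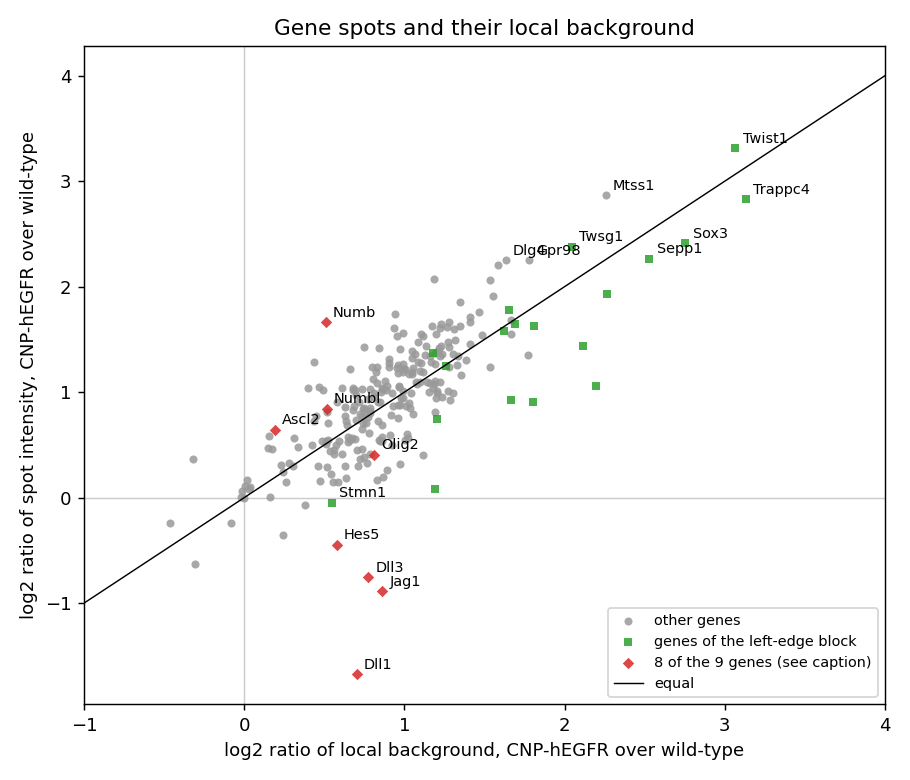
Log2 ratio of spot intensity (y axis) against log2 ratio of local background (x axis), CNP-hEGFR over wild-type, for the gene spots, with the left-edge layout block in green and 8 of the 9 genes whose deposited normalized values do not follow from their intensities in red. Spot and background ratios run along the equal line (Pearson correlation 0.82 outside the 9 genes), and Twist1, Trappc4 and Sepp1 have both ratios high.

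Outside the 9 genes, which include members of the oligodendrocyte and neuroblast lists, the cell type markers with a ratio lay within 1.21-fold of the median of all genes. In the list of neural stem cell and astrocyte markers, Nes, the nestin gene of neural progenitors, had a log2 ratio of 0.94, which is 0.11 relative to the median of all genes. The astrocyte gene S100b, called present only in CNP-hEGFR, had a lower bound of 0.92, which is 0.09 and sets no upper limit. Dcx, a gene of migrating neuroblasts, had 1.11, or 0.28 relative to the median. Both S100b and Dcx lay below the mean of the blank spots on both arrays. Among oligodendrocyte lineage genes Olig1 had 0.69, or -0.14, and Cspg4 was not called present on either array. Olig2, among the 9, had -0.58 relative to the median. Under array-median scaling the signs turned for Nes (-0.03) and Olig1 (-0.28), while Dcx had 0.14. Blood, vessel and microglia markers were not analysed here.

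Growth factor genes were present in 4 of 9 cases. The 3 with a ratio, Fgf2 (0.17), Bdnf (0.45) and the glial-derived factor gene Gdnf (0.45), had a median log2 ratio of 0.45. Among 10000 random lists matched on expression, 19.8% had a median at or below it. Under array-median scaling the median of this list was -0.52. Fgf2 and Bdnf were bright in wild-type, and the ceiling left them a rise of at most 1.30-fold and 1.92-fold. In the Hedgehog list, Shh was the 1 member of 3 with a present call. Of the Hes family, Hes6 was not called present on either array and Hes5 is among the 9 genes. Hesx1, a homeobox gene that the fixed list also held although it is not of the Hes family, had a bound of 1.02.

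As deposited, all 3 Notch ligand genes analysed had lower intensities in CNP-hEGFR, but all 3, with every other gene of this paragraph, belong to the 9 genes whose values do not follow from the array. Dll1 had a log2 ratio of -1.83, Jag1 -1.05 and Dll3 -0.91, and the Notch target gene Hes5 had -0.60. The list's median of -1.05 lay at or above that of 0.5% of 10000 random lists matched on expression, and without the 9 genes 0 members of the list are left. The Notch antagonist gene Numb had a log2 ratio of 1.505 and its relative Numbl 0.68, the transcription factor gene Ascl2 0.49, and the oligodendrocyte gene Olig2 0.25. Under array-median scaling Numb had 0.54, Numbl -0.28, Ascl2 -0.48 and Olig2 -0.72, so the signs of the last 3 turn. In the authors' deposited table the CNP-hEGFR over wild-type ratio was 0.215 for Dll1, 0.639 for Jag1, 0.392 for Dll3, 0.660 for Hes5, 3.60 for Numb, 1.71 for Numbl, 2.04 for Ascl2 and 1.97 for Olig2.

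These 9 genes, among them Ascl2, Dll1, Dll3, Hes5, Jag1, Numb, Numbl and Olig2, are all the genes on the array whose deposited values do not follow from one another. For the 279 other spots, the deposited normalized value equals the intensity minus the array minimum, divided by the same difference for the mean of the 9 normalization spots, within 0.001 on both arrays. For these 9 genes it differs on both arrays, in 18 of 18 values. Dll1 in CNP-hEGFR, for example, was deposited at 0.439 where its intensity gives 0.0394, and Dll3 in wild-type at 0.842 where its intensity gives 0.0424. In CNP-hEGFR 3 of their intensities, those of Numb (98801) and Ascl2 (85482) among them, exceed the 16-bit ceiling of 65535. All 558 intensities of the other spots are whole multiples of 2.92 within a ten-thousandth of a step, as 8-bit pixels averaged over 88 pixels give, and 14 of the 18 intensities of these genes are not. The call sheet lists 7 of the 9, along with Nkx2-2, as present on both arrays, while the layout sheet of the same report marks them absent on both. The ratios of these 9 genes are therefore given apart from those of the other genes.

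**Figure D3:**
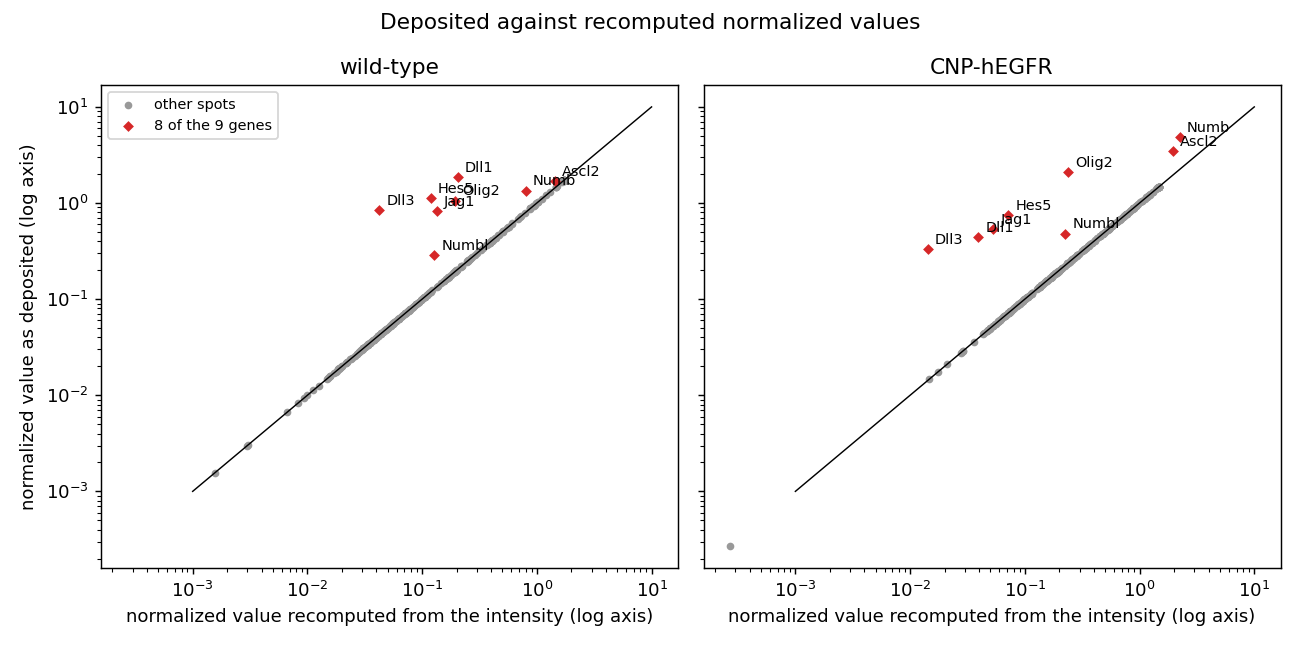
Deposited normalized value (y axis, log scale) against the value recomputed from the spot's intensity (x axis, log scale) for spots above 0, on the wild-type array (left) and on the CNP-hEGFR array (right). The other spots in grey lie on the equal line, and 8 of the 9 genes in red lie above it on both arrays, Numb in CNP-hEGFR at 4.83 against 2.24.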

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

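All tests in this part were chosen after the results were seen. Local background and control spots were not part of the comparison and carried a difference between the arrays. The local background around the gene spots was 1.87-fold higher in CNP-hEGFR at the median, and control and blank spots below the ceiling were 1.94-fold brighter.

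Most genes were higher in CNP-hEGFR after Gapdh and Ppia scaling. A genotype effect on most genes as the whole cause is argued against by the control spots. Gene spots exceeded them by a median log2 ratio of 0.0305 (standard error of the control median 0.17), where the genes themselves had 0.99. That standard error covers spots on 1 pair of arrays, some repeating 1 probe, and not a spread between arrays or animals. A brighter exposure or stronger labelling of the whole array may account for much of the rise, with a median log2 ratio of 0.96 for the control spots. Saturated normalization spots may add to it, since the housekeeping and rRNA spots below 95% of the ceiling had a median log2 ratio of 0.58 and those near it 0.00. A smaller genotype effect on many genes stays open, because each genotype has 1 array.

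The 9 genes with values that do not follow from the array were weighed against 3 technical explanations, and no biological explanation was tested because the pattern lies between columns of the same array. Spot areas reset by a user are argued against, since 3 intensities exceed the 16-bit ceiling and the normalized values do not follow from the intensities. Averages over further arrays are argued against for 4 deposited normalized values, which lie, within 1e-09, exactly 0.4 (Dll1 in CNP-hEGFR), 0.8 (Dll3 in wild-type) and 0.16 (Numbl in wild-type) above the recomputed value or at 10 times it (Jag1 in CNP-hEGFR). The 3 intensities above the ceiling argue against them too, since a mean of intensities on the 16-bit scale cannot exceed 65535. For the other values averages stay open. Values changed between image analysis and deposit, for a reason not given in the sources used here, may account for them. Of the 14 intensities off the pixel step, 10 return to it when a multiple of 1000 is subtracted (1.30 by chance) and 13 when it is added or subtracted (3.07 by chance). Multiples of 100, which include those of 1000, were also tried. They return 13 when subtracted (6.78 by chance). With either sign they return 14 where chance gives 12.9, which decides nothing. With the multiples of 1000 subtracted, Dll1 had an unscaled CNP-hEGFR over wild-type ratio of 1.48, Jag1 1.497 and Hes5 1.87, below the 1.99 of the median gene spot. The hypothesis of changed values, found and tested on the same values, therefore gives no direction for these genes.

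Strongly raised spots lay at the left edge of the CNP-hEGFR array, in layout lines 18 to 22 and the first 4 columns, and 4 of the 7 genes outside the 9 that were at least 2-fold above the median of all genes lie there. A genotype effect on the 19 genes of this block is not decided. The median log2 ratio of spot over local background there minus that elsewhere was -0.37 (standard error 0.13, a spread between spots and not between arrays). Local background was itself high beside bright spots, so a rise of the block's spots could raise it too. The ratio therefore cannot separate label from expression. A local rise of label on the membrane may account for the raised spots, since the local background in the block had a median log2 ratio of 1.80 against 0.89 elsewhere (SD 0.40). The housekeeping spot Rps27a in the block was 4.85-fold brighter, with a local background 4.72-fold higher. A difference in the genes of the block, as a set or singly, stays open.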

How the results depend on the processing

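Alternatives with the 9 genes left out, unsaturated spots, local background or layout-sheet calls were chosen after the data were seen. No paired analysis was possible because each group holds 1 sample. Actb scaling and leaving out repeat arrays were not run. Without replicates, a ratio counts as moved when it shifts by 1.5-fold or more, and a count when it differs by over 1.5 times. The 50 genes higher and 2 lower became 8 and 8 under array-median scaling, 7 and 4 with the 9 genes also left out, 7 and 10 under scaling to median local background, and 2 and 6 for each spot over its own local background among the 85 genes present on both arrays (39 and 2 there without that division). Scaling to unsaturated Gapdh and Ppia spots, of which the Gapdh spot had no present call, gave 30 higher, and no filter on absent calls 96. Subtraction of the blank mean left 26 genes and gave 12 higher. Only 3 of these 12 are among the 50, and 2 are among the 9 genes. Lower genes numbered 1 with Gapdh alone, 0 without the 9 genes and 0 with layout-sheet calls. The 1.5-fold threshold gave 78 higher and 4 lower, the 3-fold threshold 10 and 1. Above the mean of the blanks plus 2 SD, 11 genes were detected in wild-type and 12 in CNP-hEGFR, against 91 and 103 by the calls. Some of the 9 genes are in these counts. The Notch ligand median of -1.05 became -2.02 under array-median scaling, -2.07 under median local background and -1.75 over own background. The growth factor median of 0.45 became -0.52 under array-median scaling (also without the 9 genes), -0.57 under median local background and -0.41 over own background. Of the genes past 2-fold that the fixed rule names, Sepp1 changed sign, to -0.26 over its own background, and so did Efna5 (-0.12) and Sema4a (-0.18), named outside it. Further genes past 2-fold, not listed here, also changed sign over their own background. Array-median scaling lowered 38 named ratios by 0.97, while Gapdh alone or Ppia alone left all 39 within 1.5-fold. Each of these scalings shifts all log2 ratios by the same amount, so the counts are not separate checks per gene. The cause was not tested beyond this, and signal over background limits all of these, since 41.7% of wild-type and 39.9% of CNP-hEGFR spots were dimmer than their local background.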

Other observations

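The tests in this part, 5 gene lists, were chosen after the data were seen. Of 9 ephrin and Eph receptor genes, 4 were present, and 3 of them were at least 2-fold higher in CNP-hEGFR: the receptor gene Epha4 (log2 ratio 1.40) and the ligand genes Efna5 (1.39) and Efnb1 (1.20), with Efnb3 at 0.79. The median over these 4 was 1.30, and 94.5% of 10000 random lists matched on expression had a median at or below it. All genes with a value had a median of 1.00, and over all 9 members, absent ones included, the median was 0.85 against 0.83 for all genes. Efna5 had a log2 ratio of -0.12 over its own local background, Epha4 0.35 and Efnb1 0.13. Epha4 and Efnb1 lay below the mean of the blank spots on both arrays. Slit ligands and Robo receptors had a median of 1.16 over 4 genes (52.7% of random lists), and 9 semaphorins a median of 0.93 (45.5%), from Sema4a at 1.47 to Sema6c at -0.07. Both Sema4a and Sema6c lie in the left-edge block, and over their own local background they had -0.18 and -1.10.

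Of 24 homeobox genes, 9 had a value and 7 of them were at least 2-fold higher in CNP-hEGFR, against 50 of all 101 genes with a value. Among the 7 were Emx2 (1.44), Lmx1a (1.30), Emx1 (1.26) and Lhx2 (1.19), all below the mean of the blank spots on both arrays. The median over these 9 was 1.19, at or above that of 79.7% of random lists. Over all 24 members, absent ones included, it was 0.78, below the 0.83 of all genes. Under array-median scaling the values of Emx2, Lmx1a, Emx1 and Lhx2 were 0.47, 0.33, 0.29 and 0.22, and over their own local background 0.29, 0.05, 0.20 and 0.01. Among neurotrophic factors 2 genes, Gdnf and Bdnf, had a ratio, too few for a median.

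The ratio column of the authors' deposited table equals the quotient of its own normalized columns for 278 spots outside the 9 genes, and for 0 of the 9: the table gives 3.60 for Numb where its columns give 3.58. The call sheet's footer states 32.5% present spots in wild-type and 36.9% in CNP-hEGFR, equal to 89 and 101 of 274, while its own cells hold 99 and 111 and the layout sheet 91 and 103.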
